A study of Homo sapiens with 6 samples.

How the data were processed

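The series holds iCLIP libraries (individual-nucleotide resolution UV crosslinking and immunoprecipitation) from HEK293T cells, a human embryonic kidney line. Per the labels' protocols, cells received 3 µg of plasmid per 10 cm plate by calcium phosphate, 24 h after seeding, and were exposed to UV light of 254 nm at 150 mJ/cm2. RNA was trimmed with RNase I, pulled down with an antibody against GFP, joined to an infrared adaptor, run on a gel and moved to nitrocellulose, and the cDNA was circularised and amplified by PCR. The plasmid encoded GFP fused to TIS11B in 3 libraries and GFP alone in 3 libraries, and groups and replicate numbers came from the sample titles.

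Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with STAR to hg38, with no versions given. The peak caller, its settings and the handling of PCR duplicates are not given in the sources used here. The deposited values are a peak list per library, with chromosome, start, end, strand and a whole-number score for each peak. What the score counts is not stated. The lowest score was 10 in each list, and peaks were 2 to 201 nt wide, which describes the lists and not a known setting. Read depth per library is therefore unknown, and list length and score totals stand in its place. Molecular identifiers are not stated, so all binomial intervals below cover counting error only.

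Each peak was placed by its centre, on its own strand, against GENCODE v44 on hg38, in the order 3' UTR, coding sequence (CDS), 5' UTR, exon of a noncoding gene, intron and outside genes. The 3' UTR of a gene was the union over its coding transcripts, joined end to end, so it can include parts of alternative isoforms. Shares were compared between groups by 2-sided exact permutation tests over the 10 distinct splits of 3 against 3 libraries, whose smallest possible p is 0.1. Single shares carry exact binomial (Clopper-Pearson) intervals at a level of 95%. Overlap between libraries meant at least 1 shared nt on the same strand. Its expectation came from 100 circular shifts of the peaks inside each joined 3' UTR, whose smallest possible p is 0.0099.

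Motifs were searched in windows of 25 nt either side of the peak centre in 3' UTRs of at least 101 nt, against the same 100 shifts per library, and the 15 arrangements of 4 U and 2 A and the 4096 sequences of 6 nt were ranked in the same way. Genes with a 3' UTR peak in all 3 GFP-TIS11B libraries formed the reproducible set, out of 18733 protein-coding genes with a 3' UTR of at least 50 nt. Binding was compared by UAUUUA content with the Cochran-Mantel-Haenszel test over 10 strata of 3' UTR length. Each gene list was tested with a 2-sided Fisher's exact test and Benjamini-Hochberg adjustment over 15 lists, at a threshold of 0.05. The lists held known AU-rich element targets of the ZFP36 family, immediate early genes, cell cycle regulators, apoptosis regulators, mRNA decay and AU-rich element binding factors, Wnt pathway genes and TGF-beta and BMP pathway genes. The others held genes of ER translocation, glycosylation and folding, glycolysis genes, ZNF-named zinc finger genes, solute carriers, SOX, FOX and KLF transcription factors, cytosolic ribosomal proteins, nuclear-encoded respiratory chain subunits and replication-dependent histones. Genes are not independent replicates, and expression was not analysed here, so a gene that is not transcribed counts as one without a peak.

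Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the 20 genes without 3' UTR peaks in any GFP-only library that had the highest mean share of 3' UTR peak score. It also names up to 10 genes found in all 3 GFP-only libraries, by the lowest of their shares of peaks. ZFP36L1, ZFP36, ZFP36L2, CD47, CD274, ELAVL1 and CXCR4 are always named, as are up to 4 members of each list with and up to 4 without a reproducible peak. From the GFP-only ranking 1 long noncoding RNA is not printed, and a few other genes that the rule selects are not reported here. The alternatives were a stricter score threshold (the upper part of each list, from quantile 0.5), merging of peaks within 20 nt, other region orders and transcripts, and strand ignored. Others were other overlap rules, windows of 10 and 50 nt, random placement, lists thinned to the shortest, other gene backgrounds, length strata, a replicate block and each library left out. The tests of UAUUUA-holding peaks among bound genes, of CDS peaks by list and of intronic peaks against flanks 200 nt away were added after seeing the data.

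The steps were tested on simulated data. A motif was planted among 37143 peaks of GFP-TIS11B replicate 1, so that 28.2% held it with chance hits included, and 28.3% was recovered. Random positions gave p below 0.05 in 3 of 40 runs. Lists of 60 genes with an odds ratio of 3 were called in 198 of 200 draws, lists without an effect in 8 of 200, and the interval held the true odds ratio in 193 of 200. The overlap count was run on 112200 peaks against a random 60.0% of the same list and gave 60.0%, which checks the counting alone. On chromosome 21 a motif was planted at 40% of 20000 positions. The true share of 41.9% took its chance hits from the same window search, so the 41.9% recovered shows only that planted sites were found. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9.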

Results

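Contacts of TIS11B with RNA were mapped by iCLIP in HEK293T cells. TIS11B is the protein of ZFP36L1, a zinc finger protein of the ZFP36 family, which binds AU-rich elements in mRNA. The GFP-TIS11B libraries (n = 3) held 112200, 190920 and 309074 peaks with score totals of 3220568, 6182939 and 11394844, over 7.78, 11.9 and 16.9 Mb. The GFP-only libraries (n = 3), the background of the same pull-down, held 266, 530 and 1488 peaks with score totals of 9047, 17793 and 52171, over 0.0189, 0.0382 and 0.107 Mb. Mean score per covered nt was 0.414, 0.518 and 0.674 with GFP-TIS11B and 0.480, 0.465 and 0.488 with GFP only.

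The first comparison asks how much RNA was recovered with GFP-TIS11B and from which parts of genes. The mean log10 number of peaks was 5.27 ± 0.22 (SD, n = 3) with GFP-TIS11B and 2.77 ± 0.38 (SD, n = 3) with GFP only, a 316-fold difference of geometric means and 2.5 on the log10 scale. Without GFP-only replicate 3 the log10 difference was 2.70. 3' UTRs, the regulatory ends of mRNAs, held 31.9% ± 1.21 of peaks with GFP-TIS11B and 11% ± 4.30 with GFP only (SD, n = 3 each). Introns held 45.9% ± 1.87 against 21.4% ± 0.438. Exons of noncoding genes went the other way, with 1.57% ± 0.0425 against 39.7% ± 6.88, and so did mitochondrial transcripts, with 0.145% ± 0.0581 against 12.8% ± 5.33. 5' UTRs held 0.834% ± 0.0157 against 1.99% ± 0.193, and sequence outside genes 4.92% ± 0.407 against 11.9% ± 1.01. Each of these differences separated the groups completely (2-sided exact permutation test, p = 0.1, the smallest that 3 against 3 libraries allow). Within the GFP-only group shares moved with list length for noncoding exons (46.6%, 39.6% and 32.9%) and 3' UTRs (8.27%, 8.87% and 16.0%). Intron shares did not (21.1%, 21.9% and 21.2%). In number, noncoding exon peaks were more frequent with GFP-TIS11B, 1811, 2921 and 4826 against 124, 210 and 489. The group differences in share were not separated from list length. CDS shares, 14.9% ± 1.1 and 14% ± 3.45, differed by less than the spread between replicates (exact permutation p = 0.8), and without GFP-only replicate 1 the difference turned to -1.03 percentage points. With the stricter score threshold the CDS shares separated completely, by 4.21 points (exact permutation p = 0.1). Per Mb of annotated sequence, GFP-TIS11B peaks numbered 936, 1536 and 2391 in 3' UTRs and 505, 842 and 1210 in CDS of the 3 libraries. Intronic peaks numbered 25.8, 45.3 and 77.1 per Mb of whole genes, exons included. The exact 95% intervals of the 3' UTR share were narrow with GFP-TIS11B, 32.9 to 33.4% in replicate 1, and wide with GFP only, 5.26 to 12.3% in replicate 1.

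**Figure D1:**
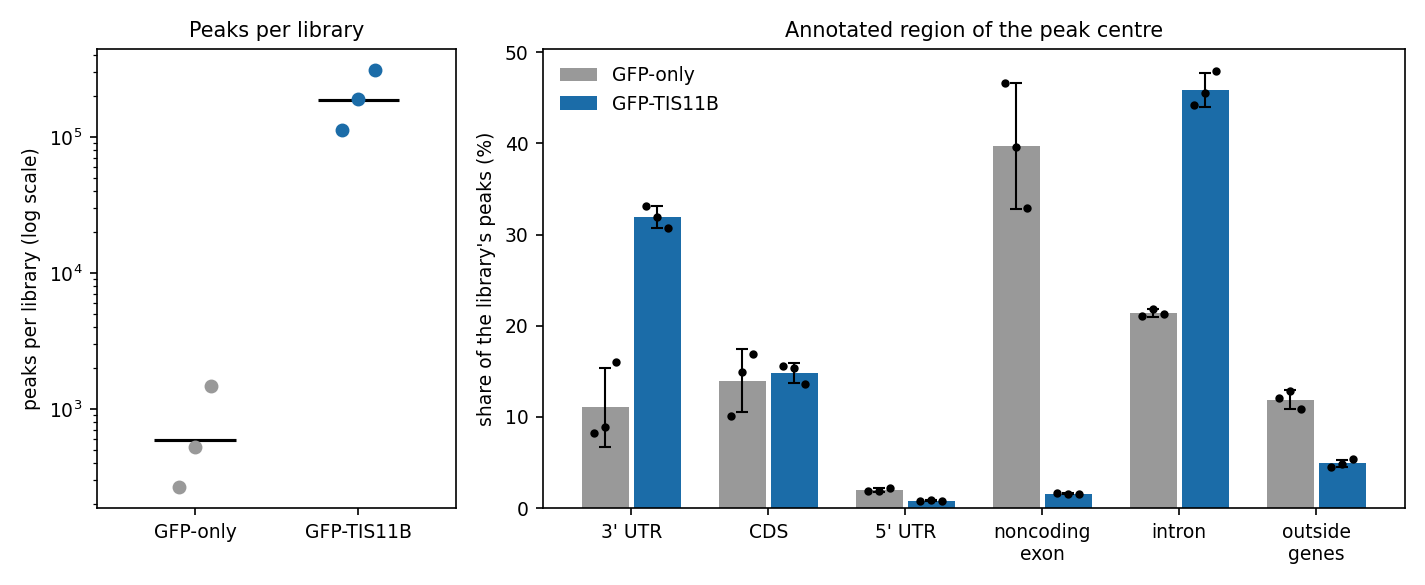
Left, number of peaks in each library on a log scale (points) with the geometric mean of each group (line). Right, share of each library's peaks by annotated region in percent; bars are means, error bars SD and points the 3 libraries of each group; 3' UTR means were 31.9% with GFP-TIS11B and 11% with GFP only.

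ZFP36L1 itself (chromosome 14, 68787660 to 68796253) held 25 CDS peaks in each GFP-TIS11B library, with 0.573%, 0.480% and 0.442% of all score, and 1 CDS peak in each GFP-only library, with 0.133%, 0.0731% and 0.0575% of all score. With GFP-TIS11B the plasmid encodes TIS11B as well, so CDS peaks of ZFP36L1 were not assigned to the cell's own mRNA or to the plasmid's. In the GFP-only libraries the plasmid encoded GFP alone, so their CDS peak cannot come from the mRNA of that plasmid. The ZFP36L1 3' UTR held 7, 16 and 11 peaks with GFP-TIS11B and 0 with GFP only. The highest GFP-TIS11B peak lay in the 3' UTR of HSPA1B, which encodes a heat shock protein (chromosome 6, from 31829979), with scores of 13959, 26178 and 33005. Its paralog HSPA1A is nearly identical, so reads of the pair are not told apart with certainty. The next lay in the CDS of ZFP36L1 in the 3 libraries, with scores of 7172, 9338 and 18785.

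Of the GFP-only peaks 88.7%, 84.3% and 78.3% overlapped a peak of GFP-TIS11B replicate 3. In the GFP-only libraries 166 genes had a peak in all 3, among them 74 nuclear protein-coding and 13 mitochondrial genes. The mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 held 25, 29 and 29 and 7, 9 and 11 peaks, and MT-ND4, a subunit of respiratory complex I, held 3, 5 and 11. The RNA helicase genes DDX17 (2, 5 and 13 peaks) and DDX6 (5, 5 and 6), the insulin receptor substrate gene IRS4 (2, 6 and 16), the snoRNA host genes GAS5 (3, 7 and 9) and SNHG1 (4, 6 and 8) and the noncoding gene ENSG00000259001 (1, 2 and 7) followed. The highest GFP-only score of each library stood at a place annotated as 5' UTR of WDR74 (554, 1043 and 2202). The region order puts 5' UTRs before exons of noncoding genes. A noncoding RNA gene at the same place would therefore not be named, and the mRNA is not shown to be the source. High scores also stood in the U1 small nuclear RNA gene RNVU1-31 (438, 725 and 1136), in the CDS of ACVR2B (519, 547 and 1112) and, in replicate 3, in MT-RNR2 (1326).

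The second comparison asks whether the GFP-TIS11B libraries found the same sites. In replicate 1, 84.6% of peaks overlapped a peak of replicate 2 and 92.1% a peak of replicate 3. In replicate 2, 51.2% overlapped replicate 1 and 84.1% replicate 3, and in replicate 3, the longest list, 35.8% overlapped replicate 1 and 53.3% replicate 2. Within 3' UTRs the overlaps were 3.63 to 4.10 times those after shifts inside the same 3' UTRs (permutation p = 0.0099 for each pair, the smallest that 100 shifts give). Peaks found in both other libraries had median scores of 19, 29 and 46, and peaks found in neither had 11, 12 and 13. Peaks of any GFP-only library overlapped 1.1%, 0.734% and 0.585% of the GFP-TIS11B peaks. When the lists were thinned at random to the length of the shortest, the mean pairwise overlap was 39.4% in place of 66.8%.

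The third comparison asks which mRNAs carried 3' UTR peaks. A 3' UTR peak was present in all 3 GFP-TIS11B libraries in 8240 of 18733 genes (44%), and 184 of the 8240 (2.23%) also had a 3' UTR peak in a GFP-only library. The median 3' UTR was 2093 nt long in these genes and 882 nt in the others. The 20 genes with the highest shares and no GFP-only 3' UTR peak together held 3.14% of 3' UTR peak score. HSP90AA1, which encodes the chaperone HSP90 alpha (chromosome 14, 102080742 to 102139699), had the highest mean share, 0.321% ± 0.0402 (SD, n = 3), with 13, 8 and 12 peaks. HSP90AA1 also had 1, 2 and 5 GFP-only peaks outside its 3' UTR. CSNK1E, a casein kinase of the Wnt and clock pathways (chromosome 22, 38290691 to 38318084), followed with 0.223% ± 0.0259, and PANK3, a pantothenate kinase of coenzyme A synthesis (chromosome 5, 168548495 to 168579368), with 0.214% ± 0.00858 and 79, 143 and 160 peaks. SDE2 (chromosome 1, 225982702 to 225999343) held 0.183% ± 0.0259, and NUFIP2 (chromosome 17, 29255839 to 29294148) 0.160% ± 0.00986. RNA-binding proteins were encoded by DDX21 (0.153%), SERBP1 (0.148%) and DDX3X (0.148%). The transcriptional regulator genes JUN, ZNF24 and AFF4 held 0.149%, 0.142% and 0.129%, and PPP1R15B, a phosphatase subunit of the stress response, 0.149%. KLHL11 (0.136%), TOR1AIP2 (0.132%), FEM1B (0.126%), BCLAF1 (0.125%), the kinase gene UHMK1 (0.118%), RABGGTB (0.117%) and the survival gene MCL1 (0.115%) were also among the 20. A UAUUUA-holding 3' UTR peak was present in each of the 3 libraries in 16 of the 20, against 28.6% of all 8240 genes. HSP90AA1, CSNK1E and RABGGTB were among those without. Such a peak was mostly not the strongest one. In replicate 1, the window of the strongest peak seen in all 3 libraries held UAUUUA in DDX3X, BCLAF1 and MCL1 alone among the 20.

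Among the genes named in advance, ZFP36L2, a relative of ZFP36L1, held 16, 20 and 26 3' UTR peaks (0.0616% ± 0.0083 of 3' UTR score, SD, n = 3). ELAVL1, which encodes the AU-rich element binding protein HuR, held 6, 6 and 11 (0.0356% ± 0.00418). CD47, a cell surface protein gene, held 4, 6 and 11 (0.0151% ± 0.00111), the chemokine receptor gene CXCR4 2, 1 and 2 (0.0108% ± 0.00102) and ZFP36 1 in each library (0.00482% ± 0.00115). CD274, which encodes PD-L1, had 1 peak in replicate 3 alone and was not in the reproducible set. None of these genes had a 3' UTR peak with GFP only. In replicate 1, the strongest ELAVL1 peak seen in all 3 libraries (chromosome 19, 7961827 to 7961934) held the window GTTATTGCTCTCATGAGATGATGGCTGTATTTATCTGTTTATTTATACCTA, with 2 UAUUUA. The ZFP36 peak (chromosome 19, 39409174 to 39409230) held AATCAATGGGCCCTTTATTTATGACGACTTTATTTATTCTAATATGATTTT, also with 2. The windows of the strongest CD47 and CXCR4 peaks held 0 UAUUUA, and that of BCLAF1 (chromosome 6, 136256657 to 136256742) held 8. CD47 still had a UAUUUA-holding 3' UTR peak in all 3 GFP-TIS11B libraries, whereas CXCR4 did not.

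**Figure D2:**
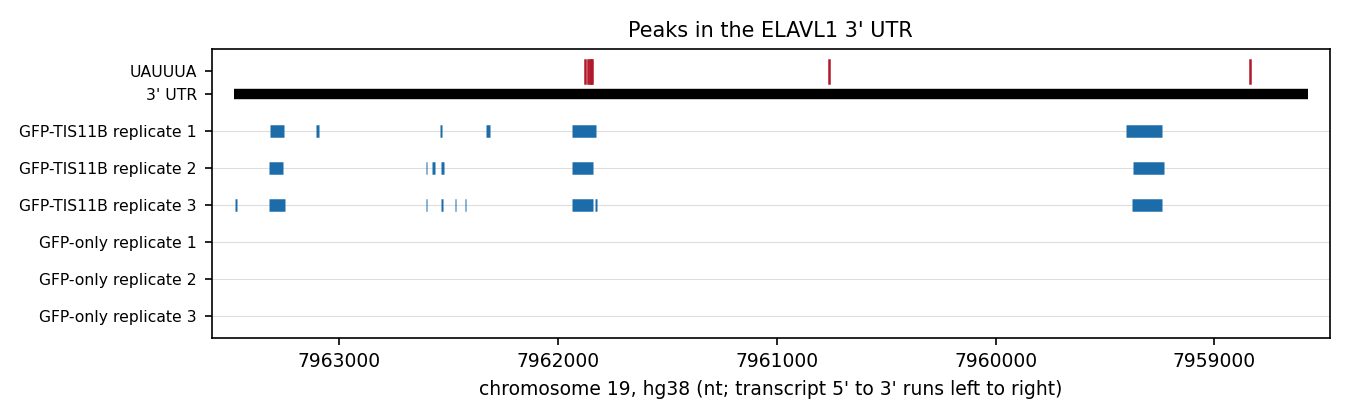
Peaks in the main block of the ELAVL1 3' UTR on chromosome 19 (hg38 positions in nt, transcript direction left to right), one line per library, with each UAUUUA drawn in red above the 3' UTR. The peak from 7961827 to 7961934 covers the cluster of UAUUUA, and the GFP-only libraries have no peak there.

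The fourth comparison asks which sequence marked the 3' UTR peaks. UAUUUA, the core of the AU-rich element bound by the ZFP36 family, stood in 10.7% ± 1.21 of 3' UTR peak windows (SD, n = 3) against 4.37% ± 0.0144 after shifts. The mean log2 ratio was 1.29 ± 0.17 (SD, n = 3; permutation p = 0.0099 in each library, the smallest possible). UAUUUA ranked 1 among the 15 arrangements of 4 U and 2 A, with a ratio of 2.46 ± 0.285 against 2.30 ± 0.262 for AUUUAU. It also ranked 1 among the 4096 sequences of 6 nt. All 15 arrangements stood above their frequency after shifts, from AAUUUU at 1.74 ± 0.0919 upwards. Part of the excess was thus shared by other sequences of the same composition. The longer UAUUUAU was 3.17 ± 0.471 times and UUAUUUAUU 4.12 ± 0.739 times as frequent as after shifts. Shorter or other motifs gave 1.84 ± 0.128 times for AUUUA, 1.73 ± 0.0652 for UUUUU and 1.93 ± 0.141 for UGUAAAUA, the Pumilio site. AAUAAA, the polyadenylation signal, stood at 0.868 ± 0.0255 times and GC-rich GGGCGG at 0.457 ± 0.0296 times its frequency after shifts. In the GFP-only libraries UAUUUA stood in 9.09%, 4.26% and 5.06% of 22, 47 and 237 windows, 4.14, 1.36 and 1.53 times its frequency after shifts (permutation p = 0.0792, 0.673 and 0.119). UUUUU stood at 1.5, 1.78 and 2.19 times there (permutation p = 0.327, 0.0099 and 0.0099) and AUUUA at 1.52, 0.687 and 1.63 times (permutation p = 0.535, 0.554 and 0.0099). With windows of 10 nt the log2 ratio for UAUUUA was 0.81.

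UAUUUA lay downstream of the peak centre. It was 2.81, 2.41 and 2.17 times as frequent in the 50 nt downstream as in the 50 nt upstream, with the highest running mean over 11 nt at 17, 14 and 14 nt downstream. The pooled GFP-only libraries gave a downstream over upstream ratio of 0.944. UUUUU stood highest within 2 nt of the centre, with downstream over upstream ratios of 1.42, 1.35 and 1.30. The pooled GFP-only libraries gave 0.596 for UUUUU, with the highest running mean at position -13. The mean position of UAUUUA minus that after shifts was 5.25 ± 1.06 nt downstream in peaks of at most 20 nt and 6.75 ± 1.41 nt in peaks over 100 nt (SD, n = 3 each).

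**Figure D3:**
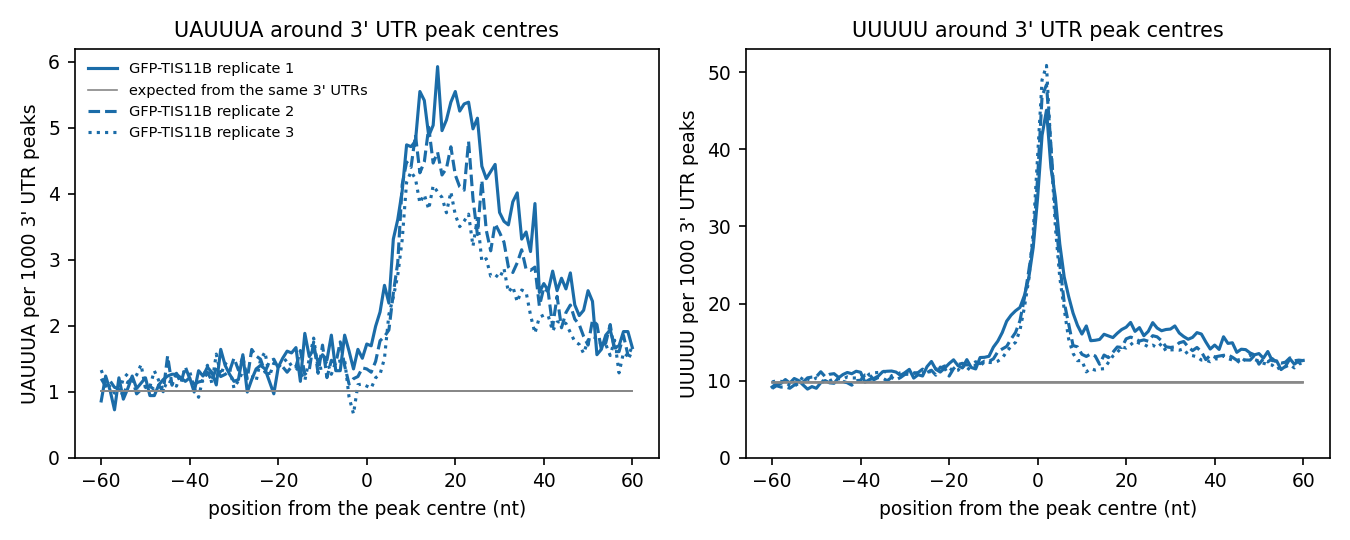
Number of UAUUUA (left) and UUUUU (right) per 1000 3' UTR peaks by position of the motif's middle from the peak centre in nt, in the 3 GFP-TIS11B libraries (blue lines) and as the rate over the same 3' UTRs (grey lines). The running mean of UAUUUA over 11 nt is highest 14 to 17 nt downstream, and that of UUUUU within 2 nt of the centre.

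Genes with UAUUUA in the 3' UTR were more often in the reproducible set. With 0 UAUUUA the share was 27.3% of 8735 genes (26.4 to 28.3), with 1 it was 49.5% of 3542 (47.8 to 51.2), with 2 it was 57.2% of 2146 (55.1 to 59.3) and with 3 or more 66.7% of 4310 (65.3 to 68.1; exact 95% intervals). Over 10 strata of 3' UTR length the odds ratio of 1 or more against 0 was 2.11 (1.96 to 2.27; n = 18733 genes, Cochran-Mantel-Haenszel p = 8.97e-94). In the stratum of the shortest 3' UTRs, 50 to 221 nt, 32.4% of 136 genes with and 10.3% of 1749 genes without UAUUUA were in the set. In that of the longest, 68.8% of 1783 and 44% of 91 genes were.

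The fifth comparison asks which gene groups were bound, by Fisher's exact test with p adjusted over 15 lists. More members than other genes had reproducible 3' UTR peaks in 12 lists and fewer in 2. Known targets of the ZFP36 family, mRNAs with AU-rich elements, had peaks in 27 of 37 members (73.0% against 43.9% of other genes, odds ratio 3.45, 1.62 to 7.98, adjusted exact p = 0.000475). Bound members included JUN (0.149% ± 0.0187), MCL1 (0.115% ± 0.009), XIAP (0.0863% ± 0.00361) and ZFP36L2, and the cytokine genes CSF2 and CXCL8, BIRC3 and CYP7A1 were not in the set. Immediate early genes, which respond within minutes to growth signals, had peaks in 26 of 34 (odds ratio 4.15, adjusted exact p = 0.00022), with MYC (0.0596% ± 0.00412) and RHOB among them and DUSP4, DUSP5, DUSP6 and EGR1 not. Cell cycle regulators had peaks in 40 of 42 (odds ratio 25.6, adjusted exact p = 7.22e-12), led by CDK1, which also had a GFP-only 3' UTR peak, CDC25A, E2F3 and MDM2, and CDC20 was not in the set. Apoptosis regulators had peaks in 28 of 33 (odds ratio 7.15, adjusted exact p = 3.10e-06), with PMAIP1 and CASP2, and BAD and FADD were not in the set.

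Factors of mRNA decay and AU-rich element binding had peaks in 53 of 56 members (odds ratio 22.6, adjusted exact p = 8.74e-15). DDX6 and IGF2BP1, which also had GFP-only 3' UTR peaks, and the decapping factor gene DCP1A (0.0927% ± 0.00918) were among those with the highest shares, and CPEB1 and TUT7 were not in the set. The Wnt pathway had peaks in 35 of 41 (odds ratio 7.46, adjusted exact p = 2.27e-07), with CTNNB1, CSNK1A1 and TLE4. BCL9L, PORCN, RNF43 and TCF7L1 were not in the set. The TGF-beta and BMP pathway had peaks in 34 of 39 (odds ratio 8.69, adjusted exact p = 1.14e-07), with SMAD5, ID4 and SKIL, and with ACVR2B, which had a GFP-only 3' UTR peak too. TGFB1, TGFB2 and ZFYVE9 were not in the set. Genes of ER translocation, glycosylation and folding had peaks in 42 of 43 (odds ratio 53.7, adjusted exact p = 1.82e-13). CANX (0.125% ± 0.0127), SRP9 (0.122% ± 0.0113) and SPCS3, each with a GFP-only 3' UTR peak too, and SSR3 had the highest shares, and SSR4 was the member without. Glycolysis genes had peaks in 17 of 19 (odds ratio 10.8, adjusted exact p = 9.08e-05), with LDHB, ENO2, PGK1 and TPI1 but not ALDOC and PFKL.

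Cytosolic ribosomal proteins had peaks in 49 of 72 members (odds ratio 2.72, adjusted exact p = 6.31e-05). RPL31, with a GFP-only 3' UTR peak too, RPS29, RPL39 and RPS4X had the highest shares, and the joined 3' UTRs of RPL31 and RPS29 were 4068 and 7468 nt long. RPL10, RPL11 and RPL17 were not in the set. Respiratory chain subunits had peaks in 52 of 77 (odds ratio 2.66, adjusted exact p = 6.31e-05), with NDUFS1 and ATP5F1B but not ATP5F1D and ATP5PO. ZNF-named zinc finger genes had peaks in 275 of 502 (odds ratio 1.56, adjusted exact p = 2.12e-06), led by ZNF24, ZNF121 and ZNF367. Solute carriers were below the other genes with 135 of 364 (odds ratio 0.747, adjusted exact p = 0.00817), although the amino acid transporter gene SLC38A2 held 0.149% ± 0.00529, with a GFP-only 3' UTR peak too. Replication-dependent histones, with short 3' UTRs and many near-identical copies, had peaks in 7 of 57 (odds ratio 0.178, adjusted exact p = 8.16e-07), with H4C8 highest and H1-3 and H2AC11 without. SOX, FOX and KLF transcription factors did not pass the test with 40 of 79 (odds ratio 1.31, adjusted exact p = 0.256). Against the genes with any GFP-TIS11B peak, ribosomal proteins (odds ratio 1.08), respiratory chain subunits (1.00) and ZNF-named genes (1.02) did not pass the test, and over length strata ZNF-named genes (1.17) and histones (0.613) did not. Against the genes with any peak, the Wnt (2.71) and TGF-beta and BMP pathways (3.16), cell cycle (9.30) and ER genes (19.5) stayed above at lower odds ratios, glycolysis genes at a higher one. Thinned lists lowered TGF-beta and BMP (3.78), apoptosis (3.26), cell cycle (9.02) and ER genes (10.9), but not ZFP36 family targets (3.48) or ZNF-named genes (1.58). Calls were also lost with thinned lists for glycolysis genes (2.35), ribosomal proteins (1.35) and respiratory chain subunits (0.899), and with the stricter threshold for ZNF-named genes (1.16). Without GFP-TIS11B replicate 1 the solute carriers did not pass (odds ratio 0.836), the Wnt pathway had an odds ratio of 41.1, and all members of the cell cycle and mRNA decay lists were in the set.

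Whether bound members carried UAUUUA at the peak was tested after seeing the data, among the 8240 genes of the set, of which 2359 (28.6%) had a UAUUUA-holding peak in all 3 libraries. Known ZFP36 family targets did so in 20 of 27 (74.1% against 28.5%, odds ratio 7.17, 2.91 to 20.1, adjusted exact p = 1.89e-05 by Fisher's exact test over 15 lists). That list was drawn up from mRNAs known for AU-rich elements, so its UAUUUA content partly follows from its choice. Members with such a peak included the immediate early genes FOS, JUN, MYC and DUSP1, the cytokine and growth factor genes TNF and VEGFA, HIF1A and ZFP36, whereas BCL2, CCND1, CCND3, DLL4, IRS1 and PIM1 were among those bound without. Factors of mRNA decay did so in 26 of 53 (49.1%, odds ratio 2.42, adjusted exact p = 0.00724), with ELAVL1, TIA1, DCP2, XRN1 and AGO2. Ribosomal proteins (4 of 49, odds ratio 0.220, adjusted exact p = 0.00356) and respiratory chain subunits (2 of 52, odds ratio 0.0990, adjusted exact p = 6.24e-05) lay below the other bound genes. The other 11 lists did not pass, among them immediate early genes with 13 of 26 (odds ratio 2.5, adjusted exact p = 0.0674) and ER genes with 12 of 42 (odds ratio 0.997). With the stricter score threshold 2 lists passed, without the decay factors (1.88) and ribosomal proteins (0.260). With lists thinned to the shortest 0 passed, at odds ratios of 3.24 for ZFP36 family targets, 1.98 for decay factors, 0.321 for ribosomal proteins and 0 for respiratory chain subunits. Respiratory chain subunits stood at 0.176 without GFP-TIS11B replicate 1 and 0.181 without replicate 2. Without GFP-TIS11B replicate 1, immediate early genes (odds ratio 2.79) and the TGF-beta and BMP pathway (3.40) passed as well, and over length strata immediate early genes (3.28) and cell cycle regulators (2.73) did.

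**Figure D4:**
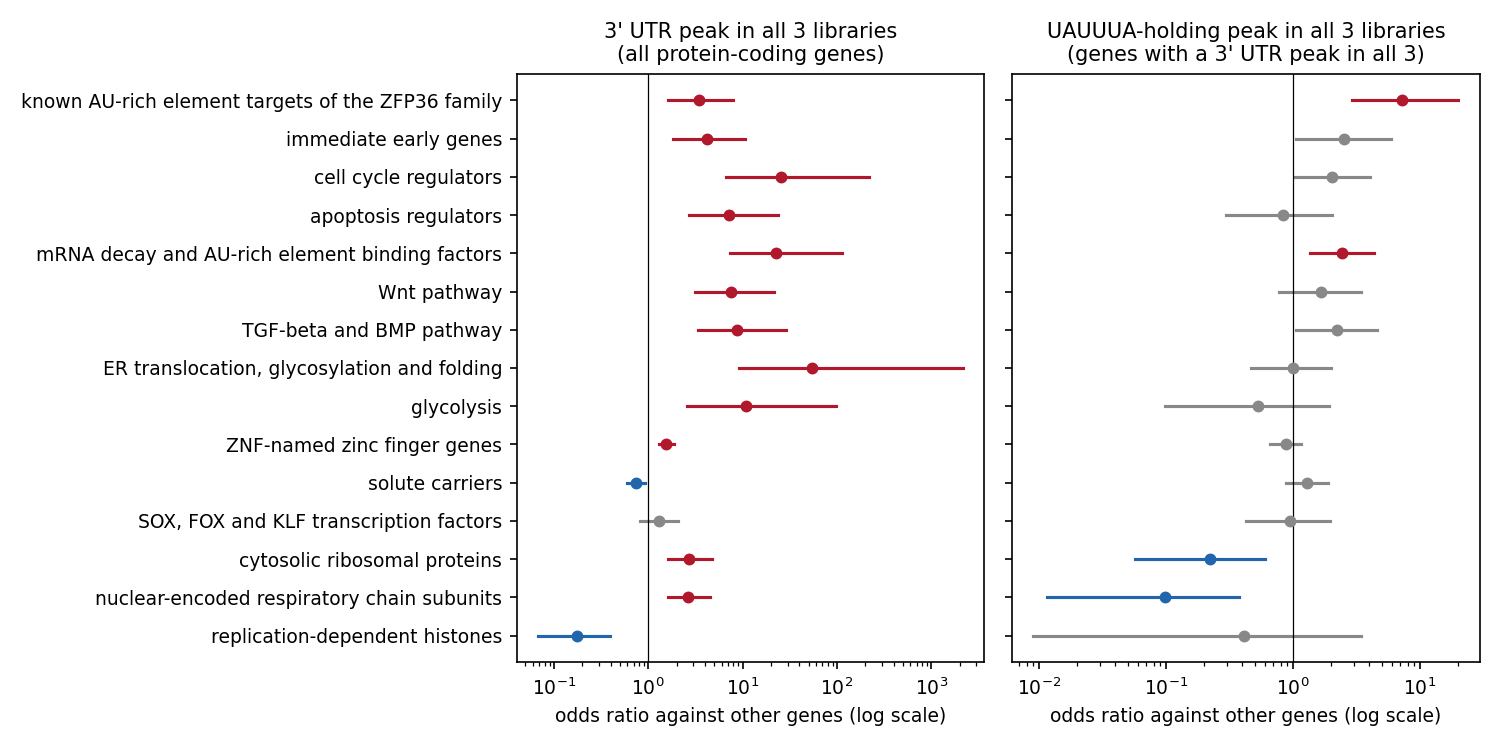
Odds ratios (points) with exact 95% intervals (lines) on log axes for the 15 gene lists. Left, a 3' UTR peak in all 3 GFP-TIS11B libraries against other protein-coding genes; right, a UAUUUA-holding peak in all 3 against other bound genes; red lists lie above and blue lists below the other genes at an adjusted p under 0.05, such as known ZFP36 family targets at 3.45 and 7.17.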

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

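All tests in this part were chosen after the UAUUUA content of intronic peaks was seen, although the bounds that decide them were set before their values were known. UAUUUA stood in 40.5% ± 2.77 of intronic peak windows of the GFP-TIS11B libraries (SD, n = 3) and in 4.42% ± 0.0845 of windows 200 nt away, a ratio of 9.18 ± 0.783. The value stood out because the report's motif comparison used 3' UTR peaks alone, and because the GFP-only libraries gave ratios of 0.857, 2 and 0.75 on 56, 116 and 316 intronic peaks. 3' UTR peaks gave a ratio of 2.57 ± 0.345 and CDS peaks 0.689 ± 0.053 against flanks 200 nt away on the genome. Flanks of CDS peaks can thus lie in introns, and they held UAUUUA in 4.52%, close to the 4.42% of intronic flanks. The CDS ratio therefore does not compare CDS peaks with other coding sequence. Of all UAUUUA-holding peaks of a library, introns held 75.2% ± 1.29 and 3' UTRs 13.9% ± 1.45. Among the 15 arrangements of 4 U and 2 A, UAUUUA ranked 1 at intronic peaks, followed by AUUUAU at 7.82 ± 0.81 and UAUUAU at 4.76 ± 0.3.

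For the ratio of 9.18, unannotated 3' UTRs or exons beside the exons used here were argued against. Intronic peaks over 5000 nt from any such exon of their strand still gave 8.60 in the lowest library and 9.83 in the highest. These exons were those of noncoding genes and of the coding transcripts that defined the regions. Exons of other transcripts of protein-coding genes counted as intron and were not tested apart. A general excess of AU-rich sequence stays open, because the median ratio of the 14 other arrangements reached 3.48 in the highest library and was 0.344 to 0.406 of that of UAUUUA, between the bounds set for and against it. Copies of repeated sequence also stay open for part of the signal, because up to 26.7% of UAUUUA sites at these peaks stood at 10 or more places in the genome, against 12.7% to 14.5% in flanks. No biological explanation was tested. Contact of GFP-TIS11B with unspliced RNA may add to the signal, as a hypothesis that needs nuclear and cytoplasmic fractions, not analysed here.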

How the results depend on the processing

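The CDS peak lists, the lists by UAUUUA-holding peaks, the genes without GFP-only peaks and the intronic ratios were tested only after the data were seen; the other alternatives were planned. In 99 of 107 comparisons of a main result with an alternative, leaving out the replicate block, the direction held, and so did the side of the threshold or, where there was no test, the size. Counts were taken as held within 1.5 times and other untested values within 1 SD between libraries. For overlap each library was first averaged over its partners. These rules let overlap fall from 66.8% to 47.4% (reciprocal rule) and the gene count to 6020. Tests of 3 against 3 libraries cannot pass the threshold, so for them the direction alone was judged. The log10 difference in peak number ranged from 2.33 to 2.70 with each library left out, the 3' UTR difference from 19.5 to 23.4 percentage points, the reproducible gene count from 8275 to 9259 (by construction not under the main 8240, since fewer libraries must agree; 6715 with the stricter threshold and 6020 with thinned lists) and the UAUUUA log2 ratio from 1.21 to 1.37. The CDS difference ranged from -1.03 to 2.33 and turned negative without GFP-only replicate 1, whose list was the shortest. It was 4.21 with the stricter threshold (exact permutation p = 0.1). Replicate numbers did not meet the criterion for pairs (correlations of deviations over 890 genes of 0.0702, -0.0218 and 0.0242 for equal numbers). List lengths of equal numbers did deviate together (log10 deviations of -0.224, 0.00722 and 0.216 with GFP-TIS11B and -0.349, -0.0496 and 0.399 with GFP only), so a shared preparation is not excluded. With the replicate block, which by construction cannot move a balanced mean difference, the differences were 2.5 (log10 peaks), 20.9 (3' UTR), 24.5 (intron), -38.1 (noncoding exon) and 0.879 points (CDS), and the smallest exact sign-flip p is 0.25. List length limits several values, by construction of the thinned lists: mean overlap was 39.4% after thinning, and lists by UAUUUA-holding peaks numbered 0 after thinning and 2 with the stricter threshold. With CDS peaks 9 lists passed (6 above, 3 below), and odds ratios turned for ZFP36 family targets (0.841), immediate early (0.348), apoptosis (0.801), ZNF-named (0.708), SOX, FOX and KLF genes (0.295) and histones (2.11). Solute carriers did not pass with at least 2 of 3 libraries (0.824) or among genes with a peak outside the 3' UTR (0.719), and SOX, FOX and KLF genes passed with at least 2 of 3 (1.62). Among genes with a peak outside the 3' UTR odds ratios turned for ribosomal proteins (0.985) and respiratory chain subunits (0.954), and after thinning for the latter (0.899). By UAUUUA-holding peaks they turned after thinning for immediate early (0.931), apoptosis (1.80) and SOX, FOX and KLF genes (1.72), with the stricter threshold for ER genes (1.31) and histones (1.02) and over length strata for ER genes (1.5) and histones (1.68). With a library left out, apoptosis genes ranged from 0.819 to 1.22 (highest without GFP-TIS11B replicate 2) and ER genes from 0.874 to 1.06 (above 1 without replicate 1, and 1.04 without replicate 3). The intronic UAUUUA ratio was 11 with the stricter threshold, 10.2 with windows of 10 nt and 6.98 with windows of 50 nt. Except where fewer peaks or libraries were used by construction, the cause was not tested. The low GFP-only peak numbers limit the motif and region values of that group.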

Other observations

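The tests by list of CDS peaks and UAUUUA-holding peaks were chosen after results by list were seen. Length strata and genes with any peak were planned, but the bounds for reading both, and the reading of the UAUUUA test as open, were set after those results were seen. The genes and peaks of the opening paragraphs were also chosen after their values were seen. Among protein-coding genes SLIT2, which encodes an axon guidance ligand (chromosome 4, 20251905 to 20620561), held the most intronic peaks by this mean share, with 198, 318 and 458, 0.164% ± 0.0144 of all peaks (SD, n = 3). Its receptor gene ROBO1 held 127, 190 and 302 and the fragile site gene FHIT 111, 194 and 369. The transcription factor gene DACH1 held 121, 179 and 275 and the DNA repair gene RAD51B 111, 173 and 278. These are long genes, of 369 kb for SLIT2, 1171 kb for ROBO1, 1504 kb for FHIT, 429 kb for DACH1 and 910 kb for RAD51B. The counts were not scaled by gene length, so they do not show preferred binding. In 3' UTRs, UAUUUA-holding peaks were numerous in PPP4R2 (9, 14 and 17) and MZT1 (9, 10 and 16). IRS4, which also had GFP-only peaks, held 11, 8 and 12 of them and RC3H2, a relative of the mRNA decay factor Roquin, 7, 12 and 13.

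Along joined 3' UTRs, 5 equal parts from start to end held 24.9% ± 0.439, 21.4% ± 0.111, 19% ± 0.309, 17.0% ± 0.297 and 17.6% ± 0.33 of GFP-TIS11B peaks (SD, n = 3). In GFP-only replicate 3 the same parts held 26.2%, 21.1%, 21.5%, 19.4% and 11.8%, so a higher share at the start was not particular to GFP-TIS11B. Joined 3' UTRs include parts of alternative isoforms, which was not allowed for. The HSPA1B 3' UTR peak region held 0.470%, 0.423% and 0.319% of library score with GFP-TIS11B, and 0, 0.112% and 0.0652% with GFP only. The MT-ND6 peak took 0.135%, 0.107% and 0.104% of score with GFP-TIS11B and 0.177%, 0.163% and 0.146% with GFP only. A peak outside annotated genes on chromosome 7 (3718529 to 3718595) took 0.151%, 0.0701% and 0.0433% of score with GFP-TIS11B, and 0, 0 and 0.0403% with GFP only.

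In 12 gene lists more members than other genes had reproducible 3' UTR peaks. For mRNA abundance as the cause for all 12, CDS peaks met the bound set against it, since 5 of the 12 lay above. The ZFP36 family targets (odds ratio 0.841, 0.312 to 1.96), immediate early (0.348, 0.0681 to 1.12), apoptosis (0.801, 0.270 to 1.98) and ZNF-named genes (0.708, 0.551 to 0.901) fell below 1. Except for ZNF-named genes these intervals hold 1. CDS peaks come from the same pull-down and do not measure abundance, so they bear on it only indirectly. The Wnt pathway (1.68), the TGF-beta and BMP pathway (2.02) and glycolysis (2.62) leaned above without passing, so abundance is not excluded for these lists singly. Longer 3' UTRs were argued against for 11 of the 12, which stayed above over 10 strata of length. For UAUUUA at the peaks as the common cause, 2 of the 12 lists passed (1 of them drawn up from AU-rich mRNAs), which met the bound set in advance against it. It was then read as open, since up to 4 lists passed under an alternative, although with thinned lists no list did. Ribosomal proteins (0.220) and respiratory chain subunits (0.0990), both among the 12, lay below the other bound genes, which argues against this cause for these lists. For the 5 lists above in both regions abundance cannot be told apart from selective binding, and expression was not analysed here. Against the genes with any peak 3 of 5 stayed above at lower odds ratios. These were cell cycle regulators (9.30, from 25.6), mRNA decay factors (8.22, from 22.6) and ER genes (19.5, from 53.7). Ribosomal proteins (1.08) and respiratory chain subunits (1.00) did not stay above. No biological explanation other than UAUUUA content was tested.

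GFP-only replicate 3 held 238 3' UTR peaks, 16.0% of its list, against 8.27% and 8.87% in replicates 1 and 2. Carry-over of cDNA from the GFP-TIS11B libraries as the source of all these peaks was argued against. UAUUUA stood in 5.06% of 237 such peaks (exact interval 2.64 to 8.68) but in 25.3% (19.9 to 31.4) of as many highest-scoring 3' UTR peaks of GFP-TIS11B replicate 3. Carry-over of a part is not excluded, since a mixture with background would also lower the UAUUUA share. The HSPA1B peak region, highest with GFP-TIS11B, also held scores of 0, 20 and 34 in the GFP-only libraries. The CDS of ZFP36L1, with the next highest GFP-TIS11B peak, held scores of 12, 13 and 30 there, whose source was not tested. Abundant RNA as the source stays open, because 49.2% of the 183 genes with such peaks lay in the top 10% of genes by CDS score, just under the share set in advance for it. The labels give no difference between these libraries, so no biological explanation was tested.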
